A study of Mus musculus with 4 samples.

How the data were processed

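Transcripts of splenic PMN-MDSCs of mice bearing B16-F10 tumors and of neutrophils of tumor-free mice were measured by RNA sequencing, with 2 libraries per group. Per the labels' protocols, libraries were made with an Illumina TruSeq RNA kit from total RNA. Bowtie 0.12.2 and the builds mm8 and mm9 are named in the submitters' processing notes, without a role or an order. The read counter, the annotation and the use of strand are not given in the sources used here. Some gene symbols are of a later annotation than those builds, so no coordinates are given. The annotation of GRCm38.p6 was used for gene names and for the order of neighbouring genes alone, and 16919 of 17118 symbols matched it.

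The deposited values are a signal per gene that behaves as read counts divided by 1 factor per library, as found from the values. In each library 100% of values were whole multiples of the value of 1 read, with a tolerance of 0.01. The factors were 1.01 and 1.05 in the tumor-free libraries and 0.922 and 1.02 in the tumor-bearing libraries. Each gene had at least 21 reads in total over the 4 libraries, so genes below that were filtered before deposit or left out of the table used here. Recovered reads per library were 44291442 and 46224499 (tumor-free) and 42245564 and 46915737 (tumor-bearing). At these depths the coefficient of variation beyond counting noise, which edgeR calls biological, was estimated at 4.03%. The labels do not say that the libraries of a group came from separate mice, so this spread may be technical. Genes with few reads are measured less precisely than abundant ones.

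The planned design gave tests for raw counts and for values such as CPM or RPKM. The values were neither, since they are counts scaled by library factors, and the branch for normalized values was used. Log2(value + 1) was fitted by limma 3.58.1 with a mean-variance trend in R 4.3.3, with the group as the only term. Fold changes are on that scale, which understates the change of low genes. A minimum of 1 normalised count in at least 2 libraries removed 0 genes. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and "rose" or "fell" is used for these. Gene lists, 39 fixed before the data were examined, were tested by camera (two-sided, preset correlation of 0.01) where at least 5 members were measured, with adjustment over the 37 lists tested. The melanoma list had 3 measured members and the list of sex-linked genes 0, and these lists were not tested. Some genes are members of more than 1 list, such as Clec4d in the late neutrophil and PMN-MDSC lists. Calls of different lists are therefore not fully separate results. With an estimated correlation 0 of the 20 list calls held, and 11 lists had an unadjusted p under 0.05.

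Named genes were the 10 with the largest increase and the 10 with the largest decrease among genes that passed, with a mean of at least 5 CPM in the higher group and libraries of the groups not overlapping. From each list up to 4 members with the smallest p could be named. Arg1, S100a8, S100a9, Cd274, Mpo, Elane, Ltf, Camp, Cxcr2 and Mki67 were named in every case. Some genes that this rule names are not reported here. Other genes were chosen after their values were seen and are marked so.

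The fits were tested on simulated counts of 17118 genes for the comparison of tumor-bearing with tumor-free libraries, with 200 genes changed. Limma recovered 28 of 50 genes changed 1.25-fold, 41 of 50 changed 1.5-fold, 40 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 11 unchanged genes called. Camera was tested on a separate simulation in which only the genes of a raised list were changed. It called that list and 0 of 40 unchanged lists. Each gene was simulated independently, so this could not test the preset correlation on lists of correlated genes.

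Alternatives were quantile normalization, median centring, rescaling without the 10 most abundant genes, other filters and pseudocounts (0.1 and 5), robust fitting, no trend, a replicate block, leaving out each library, stricter thresholds, leaving out genes of other cell types, an estimated correlation and fry. The rescaling replaced the deposited factors by library totals of recovered reads without the 10 most abundant genes. Tests of the recovered reads by edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, and a filter at 1 CPM of recovered reads, were added after seeing the data. Groups of 2 are too small for a count of other splits of the samples or a test for outlying libraries.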

Results

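RNA sequencing was performed on 4 libraries from C57BL/6 mice aged 8 weeks. B16-F10, a melanoma cell line of this strain, was inoculated under the skin of the tumor-bearing mice. On day 15, polymorphonuclear myeloid-derived suppressor cells (PMN-MDSCs), the neutrophil-like cells that accumulate in tumor-bearing hosts, were taken from the spleen with a magnetic neutrophil enrichment kit that removes other cells. Neutrophils of tumor-free mice were isolated in the same way, and their tissue is not named separately in the sources used here, so a difference of tissue between the groups is not ruled out. Each group had 2 libraries, and the comparison asked how the transcriptome of PMN-MDSCs differed from that of neutrophils without a tumor. The values were normalised read counts of 17118 genes. The read counts recovered from them summed to 44291442 and 46224499 in the tumor-free libraries and to 42245564 and 46915737 in the tumor-bearing libraries. Nothing in the labels says that the libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

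The libraries of a group differed by more than counting noise, with a chi-square per gene of 3.13 for the tumor-free pair and 6.36 for the tumor-bearing pair. Pairs across groups stood further apart, at 32.2 to 34.1. Over 11730 genes with a mean of at least 100 normalised counts, the SD of the log2 difference was 0.12 within the tumor-free group, 0.14 within the tumor-bearing group and 0.28 to 0.29 across groups. The libraries of the groups did not overlap for 9569 genes (55.9%), where chance gives 33.3%.

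Haemoglobin genes, the chondroitin sulfate proteoglycan gene Vcan and the membrane protein gene Ms4a6d were much higher in the tumor-bearing libraries, and the surface receptor gene Cd300c was much lower. Vcan rose from 104.2 ± 21.8 to 1308 ± 191 normalised counts (SD, n = 2 per group; log2 fold change 3.65 ± 0.13 SE, adjusted p = 5.94e-23 by limma). Ms4a6d rose from 211.6 ± 10.5 to 905.5 ± 6.37 (log2 fold change 2.09, adjusted p = 3.03e-18 by limma). Monocyte markers rose in the same libraries too (10 of 15, with 1 falling, median 0.29). Whether Vcan and Ms4a6d rose in neutrophils or through other cells was not tested. Cd300c fell from 2307 ± 48.4 to 156.1 ± 10.6 (log2 fold change -3.88 ± 0.091, adjusted p = 1.69e-28), which is 14.7-fold lower on the log2(value + 1) scale. Limma passed 1851 genes as higher and 1484 as lower at an adjusted p under 0.05, of which 124 and 181 changed at least 2-fold.

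Other genes with the largest increases were Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 (globin chains), Trim10, Bpgm (bisphosphoglycerate mutase of red cells) and Hspa1b (a heat-inducible chaperone of the Hsp70 family), with log2 fold changes of 1.78 to 3.96. Hbb-bs rose from 3853 ± 284 to 59760 ± 2004 normalised counts (15.5-fold, adjusted p = 9.87e-38). The other genes with the largest decreases were Hic1 (a transcriptional repressor, log2 fold change -1.78), Eps8l1 (-1.66), Slc6a19 (a neutral amino acid transporter, -1.55), Prg4 (lubricin, -1.39), Camkk1 (-1.35), Ramp3 (-1.35), LOC118567527 (-1.23), Pmel (-1.22) and Klrc2 (-1.16). Pmel, a melanosome gene, was lower in the tumor-bearing libraries, at 313.5 ± 26.2 against 729.2 ± 2.96 normalised counts. Cd300ld, a neighbour of Cd300c named after its values were seen, rose from 6095 ± 163 to 14210 ± 251 (log2 fold change 1.22, adjusted p = 1.39e-21). Reads of Hba-a1 and Hba-a2, of Hbb-bs and Hbb-bt, of Hspa1a and Hspa1b, and of the Cd300 and Klrc families could be split between near-identical copies, so their levels are uncertain.

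The number of calls depended on the fit and on the library factors, which the rescaling replaced by totals of recovered reads. Limma without a mean-variance trend passed 0 genes, with 3807 at an unadjusted p under 0.05, while edgeR on the recovered reads passed 1855 higher and 1559 lower and DESeq2 passed 1459 and 929. Without tumor-free replicate 1 the counts were 1011 and 731, without tumor-free replicate 2 they were 1157 and 796, and rescaling without the 10 most abundant genes gave 1218 and 2421, so that the share of higher calls was 33.5% instead of 55.5%.

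**Figure D1:**
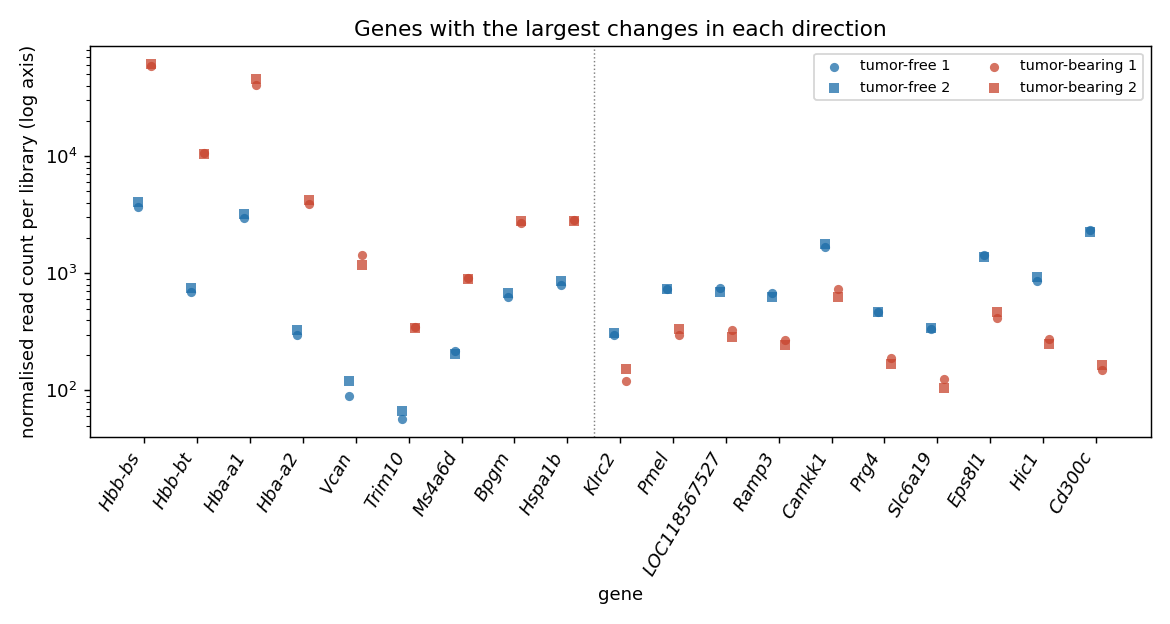
Normalised read count per library on a log axis for 9 of the genes with the largest increase and the 10 with the largest decrease, separated by the dotted line. Each point is 1 library, blue for tumor-free and red for tumor-bearing. The rule for choosing these genes required both libraries of a group to lie on the same side of both libraries of the other.

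Markers of cells other than neutrophils were present and moved with the groups. All 19 measured T cell markers fell, with a median log2 fold change of -0.51 (camera adjusted p = 2.81e-32), among them Lef1 (log2 fold change -0.94), Il7r (-0.79) and Cd8b1 (-0.65). All 12 natural killer (NK) cell markers fell, with a median of -0.73 (camera adjusted p = 2.81e-18), among them Klrd1 (-0.77), Il2rb (-0.56) and Nkg7 (-0.66). Of 21 red cell genes 18 rose and 0 fell, with a median of 0.70 (camera adjusted p = 8.44e-25). Haemoglobin genes took 0.0175% and 0.0191% of reads in the tumor-free libraries and 0.247% and 0.265% in the tumor-bearing libraries. Of 15 monocyte markers 10 rose and 1 fell, with a median of 0.29 (camera adjusted p = 2.39e-10), among them F13a1 (1.65), Ccr2 (1.02), a chemokine receptor, and Fn1 (0.72), fibronectin. With an estimated correlation the adjusted p was 0.0906 for the T cell, NK cell and red cell lists and 0.0964 for the monocyte list. B cell transcripts were abundant in both groups. Cd79a, a component of the B cell receptor named after its values were seen, had 23280 ± 1062 normalised counts in tumor-free and 23110 ± 1282 in tumor-bearing libraries (log2 fold change -0.01, adjusted p = 0.91). Of 16 B cell markers 2 rose and 1 fell (camera adjusted p = 0.702), and of 8 plasma cell markers 4 rose and 0 fell (camera adjusted p = 0.00352; adjusted p = 0.202 with an estimated correlation), led by Jchain (0.34). The lists fixed as signs of RNA quality also moved: of 13 transcripts encoded by mitochondrial DNA 6 fell and 0 rose (camera adjusted p = 0.000183; adjusted p = 0.338 with an estimated correlation), and of 51 histone genes 13 rose and 3 fell (camera adjusted p = 0.00226; adjusted p = 0.147 with an estimated correlation). The histone call also ended with the filter at 1 CPM (0.307) and without tumor-bearing replicate 1 (0.101) or 2 (0.139), and the mitochondrial call ended in fry (0.1). Leaving out 193 genes of other cell types and of immunoglobulins and T cell receptors left 1792 higher and 1429 lower genes. Of the genes left out, 52 had risen and 47 had fallen. The values of all other genes stay as they were, so this cannot show how much other cells contribute to the calls.

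More genes reported for PMN-MDSCs rose than fell, whereas several of the best known ones did not pass the test. Of 36 measured members 20 rose and 1 fell (20 and 4 adjusted over the list alone), with a median log2 fold change of 0.18 (camera adjusted p = 4.50e-08; adjusted p = 0.118 with an estimated correlation). The largest rise was that of Ccr2 (log2 fold change 1.02), which is also counted among the monocyte markers. Wfdc17 rose by 0.79 on the log2 scale, Arg2, the mitochondrial arginase, by 0.69, Ifitm1 by 0.55 and Stat3 by 0.39. The alarmin genes S100a8 (138600 ± 7485 against 136600 ± 2542 normalised counts, adjusted p = 0.829) and S100a9 (log2 fold change -0.03, adjusted p = 0.67) did not pass, and neither did Cd274, which encodes PD-L1 (-0.02, adjusted p = 0.882). Arg1, the cytosolic arginase, was near the floor at 31.5 ± 2.90 and 24.2 ± 1.02 normalised counts (adjusted p = 0.553). In the same comparison the median log2 fold change was 0.29 for monocyte markers (10 of 15 rose), 0.70 for red cell genes (18 of 21 rose), 0.61 for histone genes (13 of 51 rose), -0.51 for T cell markers (19 of 19 fell), -0.73 for NK cell markers (12 of 12 fell) and -0.25 for mitochondrially encoded transcripts (6 of 13 fell).

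Neutrophil maturation genes went both ways. Among 24 genes of late neutrophils 14 rose and 5 fell (14 and 5 adjusted over the list alone), with a median log2 fold change of 0.24 (camera adjusted p = 0.000356; adjusted p = 0.147 with an estimated correlation). Cxcr2, the chemokine receptor of mature neutrophils, rose by 0.33 and Il1r2 by 0.39, whereas Mmp9, gelatinase B, fell by 0.46. Quantile normalization ended this call (adjusted p = 0.314). Beside these genes, 10 of 15 monocyte markers (median 0.29), 18 of 21 red cell genes (0.70) and 13 of 51 histone genes (0.61) rose, and 19 of 19 T cell markers (-0.51), 12 of 12 NK cell markers (-0.73) and 6 of 13 mitochondrially encoded transcripts (-0.25) fell. Of 19 specific granule genes 5 rose and 5 fell (camera adjusted p = 0.85). Ltf, lactoferrin, fell from 83120 ± 518 to 65710 ± 3278 normalised counts (log2 fold change -0.34, adjusted p = 2.00e-07) and Camp, cathelicidin, by 0.35 on the log2 scale, whereas Mmp8 rose by 0.33. Of 11 azurophil granule genes 6 rose and 2 fell, and the list did not pass (camera adjusted p = 0.139). Mpo, myeloperoxidase, rose from 917.6 ± 95.1 to 1216 ± 122 (log2 fold change 0.41, adjusted p = 0.000222), Elane, neutrophil elastase, rose by 0.45 and Ctsg, cathepsin G, by 1.03. Without tumor-bearing replicate 2 the Elane log2 fold change was 0.29 and no longer passed. Nkg7, which the NK cell list also holds, fell. Ly6g, named after its values were seen, fell by 0.33.

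Most interferon-stimulated genes rose. Of 48 measured members 39 rose and 2 fell (41 and 2 adjusted over the list alone), with a median log2 fold change of 0.41 (camera adjusted p = 3.13e-33; adjusted p = 0.0906 with an estimated correlation). Slfn5 rose from 3138 ± 75.7 to 6435 ± 299 normalised counts (log2 fold change 1.04, adjusted p = 8.17e-18), and Oas2 (0.78) and Oas3 (0.77), which encode enzymes that sense viral RNA, and Ifi204 (0.80) rose as well. Innate receptors rose for 14 of 28 members, and 1 fell (camera adjusted p = 1.10e-05, and 0.118 with an estimated correlation). Their median log2 fold change was 0.18, with 15 higher and 3 lower adjusted over the list alone. The endosomal RNA sensors Tlr8 (0.95) and Tlr7 (0.58) and the lipopolysaccharide receptor Tlr4 (0.36) rose, and Nod1 fell by 0.31. In the same libraries 10 of 15 monocyte markers (median 0.29) and 13 of 51 histone genes (0.61) rose, and 6 of 13 mitochondrially encoded transcripts (-0.25) fell.

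Most stress and immediate early genes were higher in tumor-bearing mice. Of 34 endoplasmic reticulum stress genes 27 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.27 (camera adjusted p = 1.78e-18; adjusted p = 0.0906 with an estimated correlation). The chaperone gene Hspa5 rose from 7242 ± 242 to 9633 ± 95.2 normalised counts (log2 fold change 0.41, adjusted p = 1.41e-08), with Sdf2l1 (0.63), Pdia4 (0.38) and Ppp1r15a (0.43). Ppp1r15a is also counted in the immediate early list. Of 25 immediate early and heat shock genes 19 rose and 3 fell, with a median of 0.28 (camera adjusted p = 2.26e-14; adjusted p = 0.0964 with an estimated correlation). Among those that rose were Hspa1a (1.57) and the AP-1 subunits Jun (0.94) and Fos (0.73). The 3 that fell were Egr2 (-0.53), Egr3 (-0.46) and Nr4a1 (-0.15), named after their values were seen. Of 35 genes of NF-kB signalling and cytokines 14 rose and 9 fell (camera adjusted p = 0.015, and 0.208 with an estimated correlation). Their median log2 fold change was 0.08, with 14 higher and 11 lower adjusted over the list alone. Osm, oncostatin M, rose from 11460 ± 299 to 23140 ± 64.2 (log2 fold change 1.01, adjusted p = 1.09e-19) and Socs3, a feedback inhibitor of cytokine signalling, by 0.81. Among the 9 that fell were Cd83 (-0.41), Traf1 (-0.27), Tnf (-0.25), Icam1 (-0.25), Tnfaip3 (-0.17) and Relb (-0.16), named after their values were seen. Nfkb1 (0.04) and Nfkb2 (-0.06), also named afterwards, did not pass, so the list call does not show a rise of NF-kB signalling as a whole. The call of this list ended with quantile normalization (adjusted p = 0.323) and with a filter at 1 CPM (adjusted p = 0.0509). Among markers, 18 of 21 red cell genes (median 0.70), 10 of 15 monocyte markers (0.29) and 13 of 51 histone genes (0.61) rose in these libraries too, and 6 of 13 mitochondrially encoded transcripts (-0.25) fell. Of 8 plasma cell markers 4 rose and 0 fell (median 0.16). Some of the plasma cell markers that rose are also counted in the endoplasmic reticulum stress list.

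Part of the cell cycle genes rose, by small amounts. Of 53 measured members 25 rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 fold change of 0.21 (camera adjusted p = 1.32e-09; adjusted p = 0.0964 with an estimated correlation). Pcna, the polymerase clamp, rose from 5107 ± 159 to 6978 ± 11.2 normalised counts (log2 fold change 0.45, adjusted p = 4.46e-09), and Cks2 (0.47), Top2a (0.38) and Mki67 (0.21) rose as well. Mki67 did not pass without either tumor-free library. Alongside, 18 of 21 red cell genes (median 0.70) and 13 of 51 histone genes (0.61) rose, and 6 of 13 mitochondrially encoded transcripts (-0.25) fell.

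Most sterol synthesis genes fell. Of 24 cholesterol synthesis genes 15 fell and 1 rose (16 and 1 adjusted over the list alone), with a median log2 fold change of -0.39 (camera adjusted p = 3.02e-08; adjusted p = 0.0964 with an estimated correlation). Cyp51, a demethylase of the pathway, fell from 1119 ± 51.3 to 759.5 ± 53.3 normalised counts (log2 fold change -0.56, adjusted p = 9.42e-07), and Srebf2 (-0.35), which encodes a transcription factor of the pathway, fell as well. All 19 T cell markers (median -0.51), all 12 NK cell markers (-0.73) and 6 of 13 mitochondrially encoded transcripts (-0.25) fell in the same libraries. Of 39 genes of lipid uptake and oxidation 8 rose and 3 fell (camera adjusted p = 0.0166, and 0.323 with an estimated correlation). Their median log2 fold change was 0.07, with 9 higher and 5 lower adjusted over the list alone. Among those that rose were the scavenger receptor gene Msr1 (1.29) and Dgat2 (0.89) and Plin2 (0.78), which act in triglyceride storage. Of 23 glycolysis genes 9 rose and 2 fell (camera adjusted p = 0.0166, and 0.35 with an estimated correlation). Their median log2 fold change was 0.06, with 9 higher and 3 lower adjusted over the list alone. Pfkfb3 (0.46) and the glucose transporter gene Slc2a1 (0.35) were among those that rose. Beside the lipid and glycolysis genes, 10 of 15 monocyte markers (median 0.29), 18 of 21 red cell genes (0.70) and 13 of 51 histone genes (0.61) rose. Quantile normalization ended the calls of both lists (adjusted p = 0.0524 for lipid genes and 0.342 for glycolysis), as did the filter at 1 CPM (0.0647 and 0.0642), and the glycolysis call also ended with rescaling (0.0985), with fry (0.0737) and without tumor-free replicate 2 (0.0617) or tumor-bearing replicate 2 (0.077). Of 74 respiratory chain genes 1 rose, Atp5o (0.21), and 1 fell, Ndufb4 (-0.47) (camera adjusted p = 0.9). Both lost their call without tumor-free replicate 1 and without tumor-bearing replicate 2, and Ndufb4 also without tumor-free replicate 2. Genes of the NADPH oxidase and redox control went both ways, with 6 higher and 7 lower of 29 (camera adjusted p = 0.706), including Hmox1 (0.46) and Ncf1 (-0.50), which encodes an oxidase subunit.

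**Figure D2:**
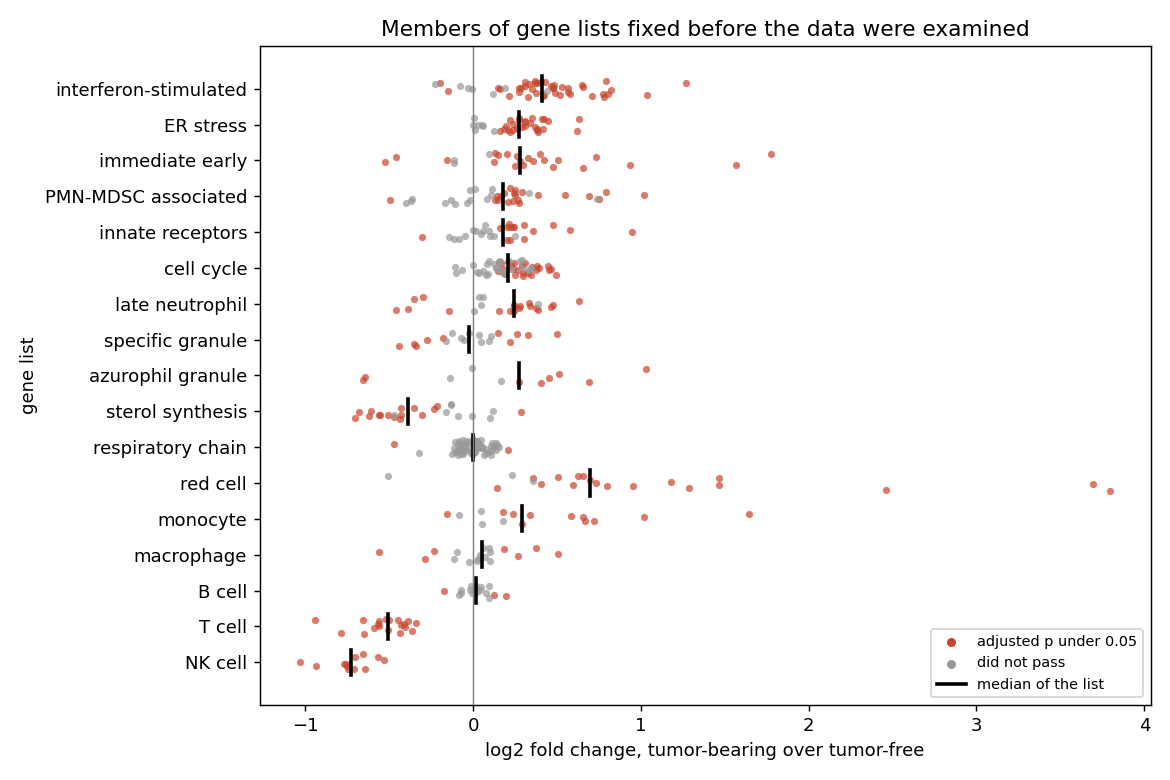
Log2 fold change of tumor-bearing over tumor-free libraries for the measured members of 17 gene lists, with 1 point per gene and a black bar at the median of each list. Red points passed limma at an adjusted p under 0.05 and grey points did not, and all points of the T cell and NK cell lists lie below 0.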

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

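The tests of the recovered reads by edgeR and DESeq2 and the filter at 1 CPM were chosen after seeing the data. The main counts were 1851 higher and 1484 lower genes. Rescaling without the 10 most abundant genes gave 1218 and 2421, and it moved the median log2 fold change of expressed genes from 0.016 to -0.0501. Limma without a trend gave 0 and 0 (3807 genes at an unadjusted p under 0.05). A minimum absolute log2 fold change of 1 gave 124 and 181, an adjusted p under 0.01 left 887 lower genes, and DESeq2 passed 929 lower genes. Stricter thresholds pass fewer genes by construction, and apart from rescaling the cause for the other settings was not tested. Leaving out each library gave 1011 to 2114 higher and 731 to 1750 lower genes; the lone library of a group is then assumed to vary like the other group. The lowest counts came without tumor-free replicate 1, and without tumor-free replicate 2 they were 1157 and 796. EdgeR shared 1826 higher and 1464 lower genes with the main test. Quantile normalization gave 1387 and 1414, and median centring 1623 and 1720. The labels share replicate numbers but nothing says that these pair mice, and deviations of same-numbered libraries correlated at -0.012 across genes; the replicate block gave 1809 and 1490 genes, and 16 higher and 4 lower lists.

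Of the lists, 16 were higher and 4 lower, against 0 and 0 in camera with an estimated correlation (11 lists at an unadjusted p under 0.05) and 14 and 4 in fry, where the glycolysis (adjusted p = 0.0737), myeloid transcription factor (0.0632) and mitochondrially encoded (0.1) lists lost their calls and the stroma and endothelium list, lower, passed (0.0481). Under quantile normalization 11 were higher and 5 lower. The histone list was not called with the filter at 1 CPM (adjusted p = 0.307) or without either tumor-bearing library (0.101 and 0.139). The glycolysis list was also not called with rescaling (0.0985), with the filter at 1 CPM (0.0642), or without tumor-free replicate 2 (0.0617) or tumor-bearing replicate 2 (0.077). The filter at 1 CPM ended the calls of the lipid (0.0647) and NF-kB (0.0509) lists too.

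No list and no named gene that passed turned direction under the alternatives run. The MHC class I list, lower but not past the threshold, passed under quantile normalization (adjusted p = 0.00663) and rescaling (0.0433), and the basophil and mast cell list under rescaling (0.0385) and without tumor-free replicate 2 (0.0279) or tumor-bearing replicate 1 (0.0297). Lists that did not pass turned under quantile normalization with adjusted p of 0.342 (NADPH oxidase and redox), 0.298 (adhesion), 0.507 (apoptosis), 0.275 (MHC class II), 0.0525 (ribosomal proteins), 0.157 (B cell) and 0.99 (dendritic cell). Rescaling without the 10 most abundant genes turned the same 7 with 0.866, 0.994, 0.922, 0.564, 0.333, 0.648 and 0.922 in that order. Median centring turned MHC class II (0.954) and ribosomal proteins (0.869), the filter at 1 CPM turned ribosomal proteins and dendritic cell (both 0.998), the replicate block turned dendritic cell (0.97), and fry turned apoptosis (0.444) and dendritic cell (0.0884). Leaving out some of the libraries turned 7 lists. In what follows the range is over all 4 omissions, whether or not they turned the list. Without tumor-bearing replicate 1 the specific granule (adjusted p = 0.599; range 0.224 to 0.958) and progenitor (0.996; range 0.795 to 0.996) lists turned, and without tumor-free replicate 1 the macrophage list (0.884; range 0.0617 to 0.884). The respiratory chain list turned without tumor-free replicate 1 (0.671) or tumor-bearing replicate 1 (0.402; range 0.175 to 0.671). MHC class II turned without tumor-free replicate 2 (0.948) or tumor-bearing replicate 2 (0.88; range 0.532 to 0.948), as did ribosomal proteins (0.622 and 0.05; range 0.05 to 0.622). The dendritic cell list turned in each omission except that of tumor-free replicate 2 (range 0.819 to 0.958). Of single genes that did not pass, the H2-Ab1 log2 fold change turned under quantile normalization (-0.026). Leaving out each library moved the S100a8 log2 fold change from -0.0746 to 0.0357, the Cd274 log2 fold change from -0.0962 to 0.0644 and the Cd79a log2 fold change from -0.0674 to 0.0459. The cause of these turns was not tested. At this depth genes with few reads limit the test, as Arg1, at 31.5 and 24.2 normalised counts, shows with an SE of 0.36.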

Other observations

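Transcripts encoded by mitochondrial DNA, fixed with the histone genes as signs of RNA quality, were lower in tumor-bearing libraries, with 6 of 13 falling and 0 rising, a median log2 fold change of -0.25 (camera adjusted p = 0.000183; adjusted p = 0.338 with an estimated correlation). ND5 fell from 52030 ± 5076 to 39310 ± 8868 normalised counts (SD, n = 2 per group; log2 fold change -0.42, adjusted p = 3.95e-05 by limma). The ND5 log2 fold change was -0.65 without tumor-bearing replicate 1 and -0.19 without tumor-bearing replicate 2. Of 51 histone genes 13 rose and 3 fell, with a median of 0.61 (camera adjusted p = 0.00226; adjusted p = 0.147 with an estimated correlation), and the leading members had low counts, such as H1f3 at 17.4 and 59.0. The histone call ended with the filter at 1 CPM (adjusted p = 0.307) and without tumor-bearing replicate 1 (0.101) or 2 (0.139). Genes of iron handling and ferroptosis rose for 9 of 21 members and 1 fell (camera adjusted p = 0.000384, and 0.147 with an estimated correlation). Their median log2 fold change was 0.06, with 9 higher and 4 lower adjusted over the list alone. Fth1, ferritin heavy chain, rose from 113000 ± 769 to 163100 ± 9504 (log2 fold change 0.53), Steap4, a metalloreductase, rose by 0.77, and Alox15 fell by 0.96. Of 32 myeloid transcription factors 15 rose and 4 fell (camera adjusted p = 0.00747, and 0.377 with an estimated correlation). Their median log2 fold change was 0.11, with 15 higher and 6 lower adjusted over the list alone. Id1 (1.14) and Klf4 (0.66) were among those that rose. The call of this list ended with quantile normalization (adjusted p = 0.275) and in fry (0.0632). Red cell genes (18 of 21, median 0.70) and monocyte markers (10 of 15, median 0.29) rose in the same libraries as the iron and transcription factor genes, and haemoglobin genes took 0.247% and 0.265% of reads there, against 0.0175% and 0.0191% in tumor-free libraries.

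The other lists did not pass. Members rose and fell in 7 and 6 of 25 genes of adhesion and chemotaxis, 6 and 5 of 25 of apoptosis, 1 and 1 of 12 of MHC class II, 0 and 2 of 14 of MHC class I, 7 and 2 of 79 ribosomal protein genes, 4 and 3 of 18 macrophage, 3 and 3 of 16 dendritic cell, 2 and 2 of 8 eosinophil, 5 and 1 of 10 basophil and mast cell, 3 and 0 of 16 platelet, 2 and 0 of 12 progenitor and 1 and 3 of 10 stroma and endothelium genes. The camera direction of the ribosomal protein list was upward although its median and mean lay just below 0, and median and mean differed in sign for the NADPH oxidase, respiratory chain, apoptosis and dendritic cell lists. Within them Bcl2l1, which encodes an inhibitor of apoptosis, rose by 0.90, Fasl fell by 1.05 and Siglech, a marker of plasmacytoid dendritic cells, fell by 1.04. In the same libraries 19 of 19 T cell markers (median -0.51) and 12 of 12 NK cell markers (-0.73) fell, and 18 of 21 red cell genes (0.70) rose. Whether Bcl2l1 and Fasl changed in neutrophils or through other cells was not tested. A second list of 12 monocyte genes had a median log2 fold change of 0.347, against 0.412 for the interferon-stimulated genes (two-sided permutation p = 0.448). A larger share of monocytes as the cause of the interferon-stimulated rise had predicted a median at least as high. A lower median with p under 0.05 would have argued against it. Neither was met, and genes rather than samples were permuted, so this remains open.

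Of the tests below, the ratio of Cd300 counts and the comparison of B cell with T and NK cell markers were chosen only after the result was seen, and so was the condition on the baseline of red cell genes.

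On the log2(value + 1) scale Cd300c fell 14.7-fold while Cd300ld rose 2.33-fold, Cd300e (log2 fold change 0.67), Cd300lg (1.05), Cd300ld4 (0.49) and Cd300c2 (0.14) rose, and Cd300a and Cd300lb did not pass, all named after their values were seen. Reads moving from Cd300c to Cd300ld as the whole cause is argued against, because the gain of Cd300ld was 3.77 times the loss of Cd300c (3.57 to 3.99 over the libraries). A haplotype block that differs between the mice remains a candidate explanation. Of the 100 nearest measured genes outside the Cd300 family, 50 on each side, 10% passed limma with a change of at least 0.5 on the log2 scale, against 5.94% of 16809 other genes (one-sided Fisher's exact p = 0.0748), and the upper 95% bound of 17.6% (Clopper-Pearson) keeps this open. A response of the cells to the tumor is also open and was not tested apart from it.

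The T and NK cell markers fell while B cell markers did not follow. A lower share of all lymphocytes is argued against, because the B cell median lay 0.589 above that of the T and NK cell markers. B cell markers spanned -0.17 to 0.19, while the highest T cell marker lay at -0.34 and the highest NK cell marker at -0.53. The two-sided permutation p was 1e-05, the smallest the permutations can give. It adds no support, because the lists were known not to overlap and genes rather than samples were permuted. A lower share of T and NK cells may account for the fall: in a second list of 17 such genes, written before their values were seen, the median log2 fold change was -0.50 and 17 of 17 lay below 0. Its most abundant members were Cd2, at 6821 normalised counts in tumor-free and 5337 in tumor-bearing libraries, and Thy1, at 6556 and 4750. The enrichment kit removes such cells, and whether fewer were in the starting tissue, more were removed or the tissue differed between groups was not tested, since the tissue of the tumor-free neutrophils is not named separately in the sources used here.

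The 4 haemoglobin genes rose with a median log2 fold change of 3.83, far more than a second list of 18 red cell precursor genes, whose median was 0.401 (exact two-sided permutation p = 0.00123 over 7315 splits). The haemoglobin genes were already among those with the largest increases, so this p was largely set by their choice. It was written beforehand that such a gap would exclude a larger share of red cell precursors with an unchanged profile. That prediction was wrong in its design, because the genes of the second list already stood at a median of 5.80 CPM in tumor-free libraries, where transcripts from other cells can hide a small share of red cells. The reading was changed from excluded to open for this reason after the result was known. More red cell precursors, and a changed profile of these cells, therefore cannot be told apart here.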
